A study of Homo sapiens with 6 samples.

How the data were processed

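Total RNA of THP-1 cells was measured on single-colour Illumina bead arrays, 3 treated for 4 h with vehicle (0.1% ethanol) and 3 treated for 4 h with 100 nM 1,25D. Per the labels' protocols, the cells spent the preceding night in medium free of phenol red with charcoal-stripped serum, RNA was isolated with a column kit and checked for genomic DNA, and biotinylated cRNA was prepared with an Ambion kit for Illumina arrays. Groups and replicate numbers came from the sample titles.

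The values analysed were the authors' processed values on a log2-like scale, as deposited, for 48700 probes on each array. lumi, an R package for Illumina arrays, is named without a version per the submitters' processing notes. The background handling, the normalization between arrays and whether the scale is plain log2 or variance-stabilised are not given in the sources used here. The values are not centred per gene. Array medians were 7.0234, 7.0266 and 7.0253 for vehicle and 7.0191, 7.0246 and 7.02 for 1,25D. The 75th percentile of the probe means was 7.35, so most probes lay in a narrow band near the floor, where differences are compressed and the true fold can be understated. A second deposited table of unnormalized signals with 12 value columns was not used, because its column names match no label of a sample. Detection p-values were therefore not analysed here, and whether a gene lay above background is unknown. The number of arrays, 3 per group, limits the precision.

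The test planned before the data were examined started from unnormalized signals, with background correction and quantile normalization by neqc and a filter on detection p-values. These steps could not be run without a mapping of columns to samples, so the authors' values took their place, and the filter was the fallback fixed in advance, a probe mean above the 40th percentile of all probe means (6.98). GEO's platform annotation gave 1 gene symbol for 23686 probes, several for 35 and none for 24979. Of the probes with 1 symbol, 23650 matched the current RefSeq annotation (GRCh38.p14) by gene ID and took its symbol, and the others kept the array's symbol. That annotation served only for names and for which genes neighbour each other, since no build is named for the array. Probes with several symbols were named for none. This left 17746 probes of 15062 genes. Each gene was represented by its brightest tested probe over the 6 arrays, and 2099 genes had more than 1 tested probe. Of 93 called genes with more than 1 tested probe, 38 had a further probe of opposite sign, 0 had one called in the opposite direction, and 6 had all further probes called in the same direction. Disagreeing tested probes of named genes are given beside their values. Probes under the filter are not, among them a VDR probe at the 27.2 percentile that differed by -0.04, against 0.04 for the probe used.

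Differences were tested in 2-sided fits with limma 3.58.1 (lmFit and eBayes at their defaults) in R 4.3.3, 1,25D minus vehicle over all 6 arrays and without covariates, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The median residual SD over genes was 0.0531 on the log2 scale. The fit was tested on simulated data for this comparison, with 15062 genes of which 200 were changed. It recovered 89% of the genes changed by 0.25 and 100% of those changed by 1 on the log2 scale, and 19 of its 208 calls were false. The simulated noise was independent between genes and arrays and held no batch. The result therefore does not cover false calls from a difference between the arrays of the 2 groups. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

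For 22 gene lists fixed before the data were examined, 532 of 578 entries were on the array. The lists share members, among them CD14 in 3 lists. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 22 lists. An estimated correlation and fry were chosen in advance as further tests, and a 2-sided Fisher's exact test of the share of called members against all genes tested was added after the data were seen. Fisher's test did not match genes on intensity, and brighter genes were called more often. Of 4918 genes with a mean of 9 or more, 223 were higher and 142 lower, against 394 and 217 of all 15062. A larger called share can therefore partly follow from brighter members. Adjusted over the list alone means Benjamini-Hochberg adjustment over the tested members of that list.

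The genes named were fixed by rule before the data were examined. They were the 12 highest and 12 lowest log2 changes among called genes whose groups do not overlap, 10 genes named whatever their values (CYP24A1, CYP27B1, VDR, RXRA, CAMP, CD14, THBD, FBP1, ACTB and GAPDH), and up to 4 called members per list with the smallest adjusted p, or 1 or 2 with the smallest p where none was called. Genes known only by locus numbers were to be left unnamed, and 0 fell in that range. NRIP1, ALOX5, OSM, TREM1, CCL3, CEBPD, CD36, LMO2, PDK4 and RHOQ were named after their values were seen, as were CDKN1A and GADD45A in the list of known VDR targets.

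Settings chosen in advance for comparison were no filter on dim probes, the replicate number as a block, the mean of a gene's probes, eBayes with trend and robust, array weights, stricter thresholds and leaving out each array in turn. Quantile normalization, median centring and cyclic loess of the authors' values, filters at the 60th and 75th percentile, and gene lists less CD14, CAMP, THBD and FBP1 were chosen after the data were seen. With 6 arrays, all 10 splits into 3 and 3 were also fitted.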

Results

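THP-1 cells, an established human line from a monocytic leukaemia, were treated for 4 h with 100 nM 1,25D or with the ethanol vehicle. 1,25D is the hormonally active form of vitamin D3, and it binds the vitamin D receptor VDR, a nuclear receptor that pairs with retinoid X receptors such as RXRA to regulate transcription. The series asked which genes respond to VDR activation across the genome in these cells. RNA was measured on 6 Illumina bead arrays, 3 per group, with 48700 probes per array. The authors' processed values lie on a log2-like scale from 6.005 to 15.4, and their array medians were 7.02 to 7.03. Pearson's r across probes was 0.998 for each pair of arrays within a group and 0.996 to 0.997 between groups. Genes numbered 15062 after dim probes were left out. All changes are 1,25D minus vehicle, each group mean carries its SD over 3 arrays, each log2 change carries its SE, and adjusted p-values come from limma with Benjamini-Hochberg adjustment unless another test is named. Folds take the values as plain log2, which the sources used here do not state. The labels number the arrays of a group as replicates without saying that they came from separate cultures, so the p-values measure only the spread between these arrays.

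A small set of genes was much higher with 1,25D, led by CD14, the monocyte co-receptor for bacterial lipopolysaccharide, and CAMP, the precursor of the antimicrobial peptide cathelicidin. CD14 went from 7.98 ± 0.05 to 10.71 ± 0.06 (SD, n = 3 arrays), a change of 2.73 ± 0.05 on the log2 scale or 6.65-fold (limma, adjusted p = 1.54e-12). CAMP went from 7.70 ± 0.11 to 10.22 ± 0.06 (SD, n = 3 arrays), which is 5.73-fold (limma, adjusted p = 1.27e-11). Declines were much smaller. The deepest was that of CCNA1, an A-type cyclin, at 0.664-fold of vehicle (limma, adjusted p = 1.15e-06).

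In all, 394 genes were higher and 217 lower with 1,25D at a limma adjusted p under 0.05, which is 4.06% of the genes tested. The median change was 0.28 among the higher genes and -0.23 among the lower ones. At least 1.5-fold changes came from 65 of the higher genes and from 1 of the lower genes, CCNA1, and at least 2-fold changes from 26 and 0. The groups did not overlap for 610 of the 611 called genes, and for 21.1% of all genes tested against 10% by chance. At an unadjusted p under 0.05 the count was 2476 genes. The arrays of the 2 groups also differed among the dimmest probes. Of 19480 probes under the intensity filter, 11.9% had a p under 0.05, 606 higher and 1708 lower with 1,25D, and 9 probes lay at the array minimum on all 3 vehicle arrays and on no 1,25D array. The labels name no chip or hybridisation batch, so no fit with a batch term was possible. The lower count was 117 without 1,25D replicate 2 and 110 without 1,25D replicate 3, and the higher count was 260 without 1,25D replicate 2.

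**Figure D1:**
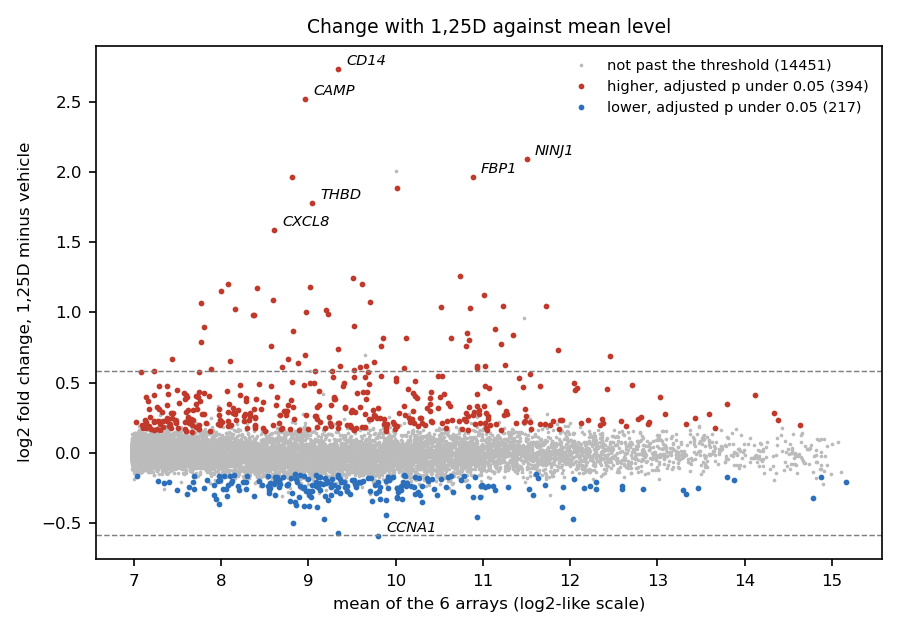
Change with 1,25D (vertical axis, log2) against the mean value of the 6 arrays (horizontal axis, log2-like scale), with 1 point per gene tested, 394 higher genes in red, 217 lower genes in blue and dashed lines at 1.5-fold. CD14 and CAMP lie at the top with 2.73 and 2.52, CCNA1 is the lowest called gene at -0.59, and the grey point at 2.01 is RHOQ, whose vehicle SD was 2.45.

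The 12 genes with the largest increases covered a range of 2.30-fold to 6.65-fold. NINJ1, a cell-surface adhesion protein that takes part in plasma membrane rupture, went from 10.46 ± 0.01 to 12.55 ± 0.06 (SD, n = 3 arrays), or 4.26-fold (limma, adjusted p = 6.43e-12). GPER1, a membrane oestrogen receptor, rose 3.90-fold, and its dimmer probe rose by 0.26 on the log2 scale. FBP1, a gluconeogenic bisphosphatase, rose 3.89-fold from 9.90 ± 0.03 to 11.86 ± 0.02 (SD, n = 3 arrays). ASAP2, a GTPase-activating protein for Arf proteins, rose 3.69-fold. THBD, the thrombin receptor thrombomodulin, went from 8.15 ± 0.07 to 9.93 ± 0.04 (SD, n = 3 arrays), which is 3.42-fold (limma, adjusted p = 5.51e-11). The neutrophil-attracting chemokine CXCL8 rose 3.00-fold. DENND6B rose 2.39-fold, PFKFB4, a regulator of glycolytic flux, 2.37-fold, the connexin GJD3 2.31-fold, and KCTD12, an auxiliary subunit of GABA receptors, 2.30-fold. The limma adjusted p of these 12 genes was at most 2.82e-09. By the rule that picked them, all 3 arrays with 1,25D lay above all 3 vehicle arrays for each gene.

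The 12 deepest declines ran from -0.59 ± 0.04 for CCNA1 to -0.37 ± 0.08 for UBALD1. GCNT1, which branches O-linked glycans, fell by 0.57 ± 0.06 (limma, adjusted p = 4.6e-05), and FILIP1L fell by 0.50 ± 0.04 (limma, adjusted p = 8.29e-06). A second FILIP1L probe fell by 0.38, while its dimmest probe stood at 0.01 without a call. The haematopoietic adaptor SAMSN1 and the myeloid repressor GFI1 each fell by 0.47. KLF2, a zinc-finger transcription factor of quiescent leukocytes, fell by 0.45 and SLA, an adaptor that dampens antigen receptor signalling, by 0.44. SLC1A3, a glutamate transporter, fell by 0.39, MS4A7 and the actin-binding protein LIMA1 by 0.38 each, and the transcription factor BCL11A by 0.38 in the brighter of its probes. Its dimmer probe changed by -0.07 and was not called. UBALD1 carried the largest spread of the 12, with a vehicle SD of 0.20 (limma, adjusted p = 0.024), and lost its call without 1,25D replicate 1 (adjusted p = 0.0819) or without 1,25D replicate 3 (adjusted p = 0.123).

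**Figure D2:**
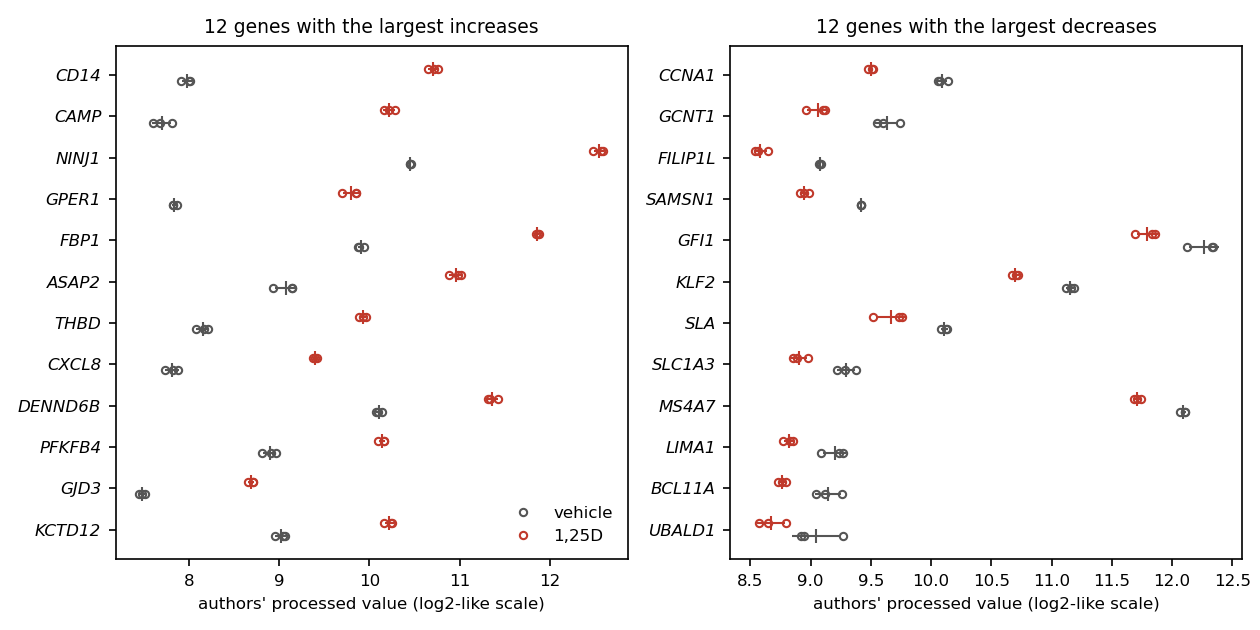
Processed value of each array (horizontal axes, log2-like scale) for the 12 genes with the largest increases (left) and the 12 with the largest decreases (right), vehicle in grey and 1,25D in red, with circles for the 3 arrays of a group, a vertical tick for the mean and a line for the SD. The groups do not overlap for any of the 24 genes, as the rule that picked them required. The scale of the right panel is narrower, with changes of -0.59 to -0.37 against 1.20 to 2.73 on the left.

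CYP24A1, the enzyme that degrades 1,25D and a classical VDR target, was not called. Its value was 7.02 ± 0.08 in vehicle and 7.15 ± 0.06 with 1,25D (SD, n = 3 arrays), a difference of 0.13 ± 0.05 with a 95% interval of 0.02 to 0.23 (limma, adjusted p = 0.223). The vehicle mean stood at the 50.2 percentile of all probes and the 1,25D mean at the 67.9 percentile, where array values are compressed near their floor. CYP27B1, which makes 1,25D, differed by -0.0038 ± 0.048 (limma, adjusted p = 0.981). VDR stood at 7.48 ± 0.02 and 7.52 ± 0.06 (SD, n = 3 arrays; limma, adjusted p = 0.682), and RXRA at 12.31 ± 0.09 and 12.23 ± 0.04 (SD, n = 3 arrays; limma, adjusted p = 0.504). The reference gene ACTB differed by 0.05 ± 0.05 (limma, adjusted p = 0.63) and GAPDH by -0.02 ± 0.04 (limma, adjusted p = 0.901), while its dimmest probe stood at 0.10 without a call and the average of its probes at 0.02. None of the 14 tested genes of vitamin D metabolism and reception was called, whether over all genes or adjusted over the list alone, and the endocytic receptor LRP2, with the smallest p after that of CYP24A1, differed by -0.07 (limma, adjusted p = 0.424). At 0.0022 that list's mean was positive and its median negative (camera, adjusted p = 0.934). LRP2 and CYP27B1 also lay in the band near the floor, with vehicle means at the 68.6 and 71.5 percentiles of all probes. Some other members of the list lay lower still. The missing calls therefore do not show that such dim genes were unchanged.

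Known VDR target genes rose as a group. Of 31 tested members, 9 were higher and 0 lower over all genes, and the counts adjusted over the list alone were also 9 and 0 (Fisher's exact test of the called share over all genes, adjusted p = 2.79e-05). The mean change was 0.35 (camera, adjusted p = 1.04e-08, and adjusted p = 0.0456 with an estimated correlation). CD14, FBP1, CAMP and THBD led the list. The other called members were the nuclear receptor corepressor NRIP1 at 0.40, the leukotriene-forming lipoxygenase ALOX5 at 0.32 in its brighter probe and 0.0044 without a call in its dimmer one, the cell cycle inhibitor CDKN1A at 0.26, the cytokine OSM at 0.23 and the stress gene GADD45A at 0.22. OSM lay in the band near the floor, with its vehicle mean at the 69.2 percentile of all probes. GADD45A lost its call without vehicle replicate 3 (adjusted p = 0.0711), without 1,25D replicate 2 (adjusted p = 0.0926) and without 1,25D replicate 3 (adjusted p = 0.0818). The list was drawn from general knowledge that includes monocytic cells, so its direction is not independent evidence. Less CD14, CAMP, THBD and FBP1, its mean was 0.07 (camera, adjusted p = 0.0399), an alternative chosen after the data were seen.

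Genes of monocyte and macrophage differentiation held the largest called share of the lists, with 8 higher and 2 lower among 31 tested (Fisher's exact test, adjusted p = 5.06e-06). Adjusted over the list alone the counts were 8 and 3. CD14 led, followed by the integrin ITGAM at 0.61 ± 0.05 (limma, adjusted p = 9.19e-06), the myeloid surface protein CD93 at 0.49 ± 0.05 and the myeloid transcription factor CEBPA at 0.35 ± 0.05. The 2 lower members were the transcription factor CEBPD at -0.24 and the scavenger receptor CD36 at -0.20, whose dimmer probe differed by -0.15 without a call. The list's mean was 0.14 (camera, adjusted p = 0.0309, and adjusted p = 0.377 with an estimated correlation). That call was lost without vehicle replicate 3 (adjusted p = 0.108), without 1,25D replicate 3 (adjusted p = 0.0597) and with CD14 left out of the list (adjusted p = 0.156).

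The called myeloid progenitor genes were mostly lower. Of 22 tested, 4 were lower and 1 higher, and adjusted over the list alone 7 were lower and 2 higher. The lower members were GFI1, the proto-oncogene MYB at -0.25 ± 0.05, the stem cell factor receptor KIT at -0.26 ± 0.05 and the survival gene BCL2 at -0.23 ± 0.05, whose dimmer probe stood at 0.02 without a call. The higher member was the haematopoietic transcription factor LMO2 at 0.23. KIT lost its call without 1,25D replicate 2 (adjusted p = 0.0668), and BCL2 without 1,25D replicate 3 (adjusted p = 0.0593). The called share exceeded that of all genes, not matched on intensity (Fisher's exact test, adjusted p = 0.0117). The mean of -0.05 was not called (camera, adjusted p = 0.182).

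Among 30 tested genes of antimicrobial defence and pattern recognition, 4 were higher and 1 lower (Fisher's exact test, adjusted p = 0.0243), and 6 and 3 adjusted over the list alone. The higher genes were CD14, CAMP, the bacterial muramyl peptide sensor NOD2 at 0.38 ± 0.04 (limma, adjusted p = 0.000104) and the receptor TREM1 at 0.22. TREM1 lay in the band near the floor, with its vehicle mean at the 52.2 percentile of all probes. The calcium-binding protein S100A8 fell by 0.26 ± 0.05 (limma, adjusted p = 0.0144) and lost its call without 1,25D replicate 3 (adjusted p = 0.075). The mean of the list was 0.19 (camera, adjusted p = 0.0385, and adjusted p = 0.377 with an estimated correlation). Without CD14 and CAMP in the list it was 0.01 (camera, adjusted p = 0.578), and the call was also lost without vehicle replicate 2 (adjusted p = 0.102), without vehicle replicate 3 (adjusted p = 0.105) and without 1,25D replicate 3 (adjusted p = 0.144). In all, 9 of the 17 alternatives ended it.

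NF-kB-driven cytokines and regulators went both ways, with 4 higher and 1 lower of 30 tested, and 7 and 3 adjusted over the list alone. CXCL8 led, and NFKBIA, the inhibitor of NF-kB, rose by 0.69 ± 0.08 (limma, adjusted p = 0.000252), TNFAIP2 by 0.27 ± 0.06 and the chemokine CCL3 by 0.34. CCL3 lay in the band near the floor, with its vehicle mean at the 71.6 percentile of all probes and a 1,25D SD of 0.20. The interleukin 1 receptor antagonist IL1RN fell by 0.21 ± 0.04 in its brightest probe. The call of IL1RN was lost without 1,25D replicate 2 (adjusted p = 0.0645), and its other probes differed by -0.17 and 0.01 without a call. TNFAIP2 lost its call without vehicle replicate 3 (adjusted p = 0.0625), without 1,25D replicate 1 (adjusted p = 0.0691) and without 1,25D replicate 2 (adjusted p = 0.0776). The share of called members exceeded that of all genes, not matched on intensity (Fisher's exact test, adjusted p = 0.0243). The mean of 0.10 was not called (camera, adjusted p = 0.13). Of 31 interferon response genes tested, 1 was called over all genes and 2 adjusted over the list alone, each lower. It was XAF1, which promotes apoptosis, at -0.27 ± 0.06 (limma, adjusted p = 0.0145), and it lost its call without 1,25D replicate 2 (adjusted p = 0.0952) or without 1,25D replicate 3 (adjusted p = 0.075). The list's mean was -0.01 and its median above 0 (camera, adjusted p = 0.862). No gene of MHC class II presentation and co-stimulation was called among 17, over all genes or adjusted over the list alone (camera, adjusted p = 0.949). CD40 differed by -0.12 and HLA-DRB1 by 0.11.

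**Figure D3:**
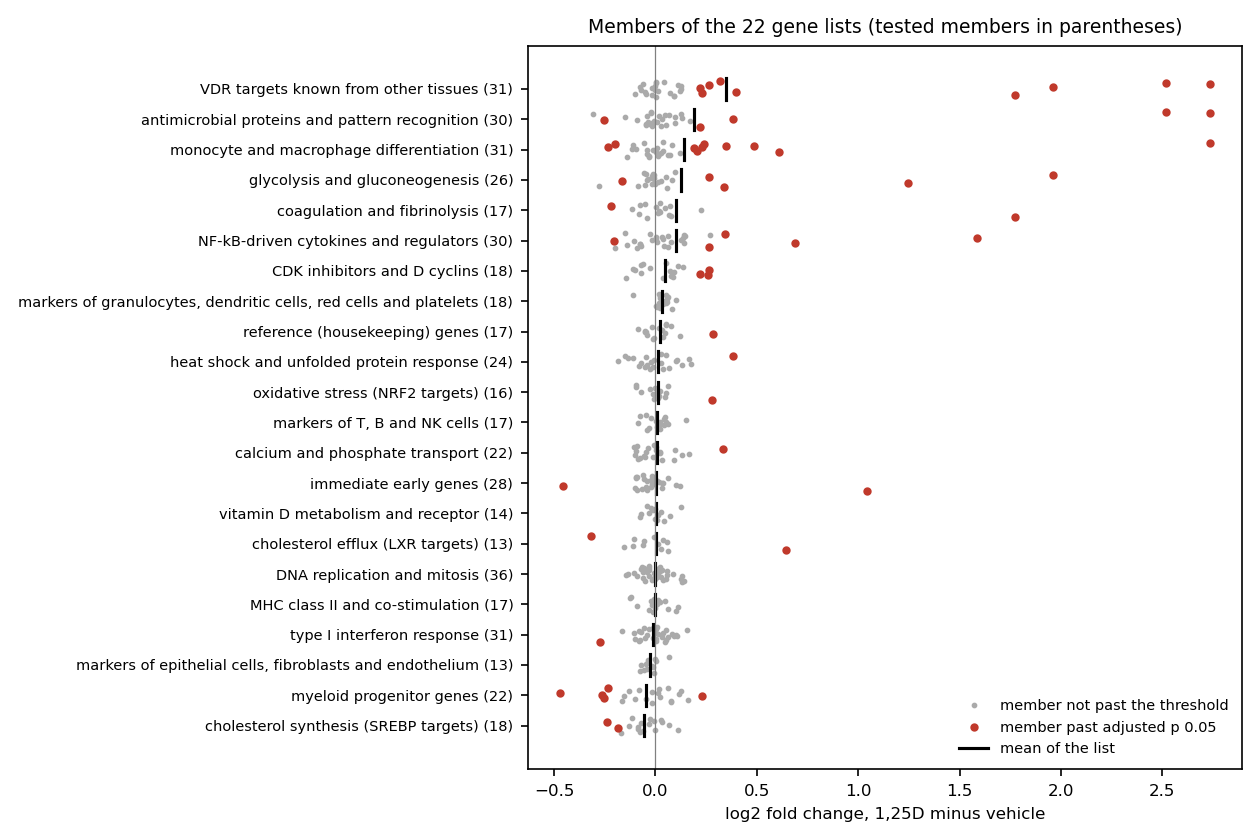
Log2 change with 1,25D of each tested member (points, red where the limma adjusted p was under 0.05) of the 22 gene lists fixed before the data were examined, with a black tick at the mean of each list and the number of tested members in parentheses. The means run from -0.06 for cholesterol synthesis to 0.35 for known VDR targets, and CD14 at 2.73 belongs to the upper 3 lists.

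No gene of DNA replication and mitosis was called among 36 tested, over all genes or adjusted over the list alone (camera, adjusted p = 0.895). TOP2A differed by 0.14 ± 0.04 (limma, adjusted p = 0.0892) and FOXM1 by -0.14 ± 0.05 (limma, adjusted p = 0.125). Among 18 CDK inhibitors, D cyclins and related genes, 3 were higher and 0 lower, and 4 and 0 adjusted over the list alone. They were CDKN1A at 0.26 ± 0.04 (limma, adjusted p = 0.00154), GADD45B at 0.26 ± 0.04 (limma, adjusted p = 0.00257) and GADD45A. The list's mean of 0.05 was not called (camera, adjusted p = 0.13).

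Glycolysis and gluconeogenesis held 4 higher and 1 lower of 26 genes tested, with the same counts adjusted over the list alone (Fisher's exact test, adjusted p = 0.0192). FBP1 and PFKFB4 were followed by the glucose transporter SLC2A3 at 0.34 ± 0.06 and the hexokinase HK1 at 0.26 ± 0.05, and PDK4, which restrains pyruvate oxidation, fell by 0.16. HK1 lost its call without 1,25D replicate 2 (adjusted p = 0.0857) or without 1,25D replicate 3 (adjusted p = 0.0816). The list's mean was 0.13 and its median slightly negative (camera, adjusted p = 0.152). In coagulation and fibrinolysis, 1 of 17 genes was higher and 1 lower, and 2 and 1 adjusted over the list alone (camera, adjusted p = 0.541). THBD rose, while F3, the tissue factor that starts coagulation, fell by 0.22 ± 0.04 (limma, adjusted p = 0.0122). That call was lost without vehicle replicate 3 (adjusted p = 0.0566), without 1,25D replicate 1 (adjusted p = 0.0644) and without 1,25D replicate 2 (adjusted p = 0.0512). F3 also lay close to the floor, at the 76.6 percentile of all probes in vehicle and the 72.4 percentile with 1,25D.

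Of 18 cholesterol synthesis genes, 2 were lower and 0 higher, and 4 and 0 adjusted over the list alone, with a mean of -0.06 (camera, adjusted p = 0.0794). HMGCS1, which makes the precursor of mevalonate, fell by 0.24 ± 0.05 (limma, adjusted p = 0.0169) and MVD, a decarboxylase of the same pathway, by 0.18 ± 0.04 (limma, adjusted p = 0.0337). HMGCS1 kept its call in 2 of the 6 fits that left out 1 array and MVD in 1. Cholesterol efflux genes gave 1 higher and 1 lower of 13, over all genes and adjusted over the list alone. The phosphodiesterase SMPDL3A rose by 0.64 ± 0.05 (limma, adjusted p = 5.56e-06), and the cholesterol exporter ABCA1 fell by 0.32 ± 0.04 (limma, adjusted p = 0.000816). The mean of that list was slightly above 0 and its median and test pointed down (camera, adjusted p = 0.677).

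Only 1 or 2 members were called in each list of this paragraph, at shares of 4.17% to 7.14% against 4.06% of all genes tested. Fisher's exact test called none of these lists (smallest adjusted p = 0.63), nor any list above given without its value. ITPR1, a calcium channel of the endoplasmic reticulum, was the 1 gene called among 22 of calcium and phosphate transport, over all genes and adjusted over the list alone, and rose by 0.33 ± 0.05 (camera for the list, adjusted p = 0.895). Immediate early genes gave 1 higher and 1 lower of 28 by both adjustments, ZFP36, which destabilises cytokine mRNAs, at 1.04 ± 0.05 (limma, adjusted p = 2.02e-08) and KLF2 (camera for the list, adjusted p = 0.677). In heat shock and the unfolded protein response 1 of 24 genes was called, the co-chaperone BAG3 at 0.38 ± 0.04, and 4 were higher and 2 lower adjusted over the list alone (camera, adjusted p = 0.677). TXNRD1, a thioredoxin reductase, rose by 0.28 ± 0.04 as the 1 of 16 oxidative stress genes called by both adjustments (camera for the list, adjusted p = 0.677). The ribosomal gene RPS18 rose by 0.28 ± 0.05 as the 1 of 17 reference genes called by both adjustments (camera for the list, adjusted p = 0.535). The mean and median differed in sign for the calcium, immediate early and heat shock lists, with each mean within 0.02 of 0.

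Markers of other cell types were not called. They covered 17 genes of T, B and NK cells, 18 of granulocytes, dendritic cells, red cells and platelets, and 13 of epithelium, fibroblasts and endothelium, with 0 calls over all genes or adjusted over each list alone. Their camera adjusted p-values were 0.789, 0.204 and 0.491. The members with the smallest p were CD79B at 0.15 and KLRB1 at -0.09, CD1C at -0.11 and PRG2 at 0.08, and TEK at -0.08 and KDR at -0.07. KLRB1, KDR and TEK lay in the band near the floor, with vehicle means at the 64.1, 66.0 and 73.4 percentiles of all probes. CD79B, CD1C and PRG2 lay above that band, at the 78.7 to 82.1 percentiles. For markers near the floor the missing calls say little. Among the 22 lists, camera called 3, all upward, and the call of known VDR targets was the 1 that held with an estimated correlation. fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, called 7.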

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

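The tests of the lowest values after quantile normalization, of probes at the array minimum, of the called share of known VDR targets and of the spread of the raised genes were chosen only after the result was seen, as was the alternative of quantile normalization.

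Probes without a gene name lay outside the comparison of genes and also differed with 1,25D. Of 11474 such probes above the intensity filter, 36 were higher and 18 lower (limma, adjusted p under 0.05), with 6 and 0 of them at least 1.5-fold. The strongest, ILMN_1656938, went from 8.28 to 9.75, a change of 1.47 (limma, adjusted p = 8.67e-11).

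The comparison called 611 genes, and the highest count in the other 9 of the 10 splits of the 6 arrays was 10, so only 1 split, the real one, gave as many, and 10 splits are too few for a share under 0.05. Quantile normalization left 90.0% of the called genes called again (550 of 611), which argues against leftover differences between the arrays' value distributions as the whole cause. Known VDR targets, listed in advance from general knowledge, were called in 9 of 31 cases, or 29.0% (exact 95% interval 14.2 to 48.0%), against 4.06% of all genes. Without CD14, CAMP, THBD and FBP1 it was 5 of 27 (exact 95% interval 6.3 to 38.1%). This argues against an array batch as the whole cause. The argument is limited, because that knowledge includes monocytic cells and the shares were not matched on intensity. A batch adding some of the calls remains open, and the size of what it could add was not tested. Of the 19480 probes under the filter, 11.9% had a p under 0.05 (606 higher, 1708 lower), against at most 4.19% in any other split. After quantile normalization 8.70% still did, which leaves the shape of the lowest values open too. The 9 probes at the minimum of all vehicle arrays and of no 1,25D array, against 0 in every other split, are consistent with different chips or hybridisations for the groups.

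Called probes under the filter had a median absolute change of 0.24, and 10 of the 104 changed at least 1.5-fold. The 9 probes at the minimum, among them the ones for ADH5, KRT7, CA7 and PCDHGA1, lay between 6.005 and 6.132 on vehicle arrays and between 6.83 and 7.72 on 1,25D arrays, and 0 of them entered the test. Among the 4870 dimmest probes the median change was -0.06, and 27.6% had a p under 0.05.

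Changes of 1.5-fold or more were nearly all upward, 65 genes against 1, and among genes with a mean of 9 or more 42 of 43 were, or 97.7% (exact 95% interval 87.7 to 99.9%), which argues against falls hidden by the compressed floor as the explanation. The median change over all genes, -0.0043, decides nothing about centring, although it was set in advance as the test, because normalization between arrays holds it near 0. The changes of the 65 genes had an SD of 0.46 against a median SE of 0.05, so the genes did not all share 1 value. Because that test was chosen after these changes were seen, it decides nothing about an offset as a cause of the imbalance. An offset that adds to part of the changes stays open. A contribution of an array batch was not excluded. Dim probes with an unadjusted limma p under 0.05 were mostly lower (606 higher, 1708 lower), opposite to this excess. The 9 probes at the vehicle minimum were instead all higher, by 0.80 to 1.62, the direction of the excess. The dim probes therefore do not decide which way a batch would act on large changes. More increases than decreases within 4 h of VDR activation may be biological, which stays a hypothesis.

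CYP24A1, a classical VDR target, was not called at 0.13 ± 0.05 (limma, adjusted p = 0.223), and its adjusted p ranged from 0.0947 to 0.456 over the alternatives. Its probe stood at the 50.2 percentile of all probes in vehicle and at the 67.9 percentile with 1,25D. This lies between the levels set in advance for and against a probe at the floor, so a level too low for this probe to report a response could account for the missing call, and a weak response at 4 h stays open, untested.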

How the results depend on the processing

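The settings of quantile normalization, median centring, cyclic loess, the 60th and 75th percentile filters and lists less CD14, CAMP, THBD and FBP1 were chosen after seeing the data. Against 394 higher and 217 lower genes, a 1.5-fold minimum left 65 and 1 and an adjusted p under 0.01 left 242 and 90, by construction. Leaving out 1 array at a time gave 260 to 361 higher and 110 to 223 lower genes, with 260 and 117 without 1,25D replicate 2 and 278 and 110 without 1,25D replicate 3, where fewer arrays entered. The replicate block gave 471 higher and 345 lower genes, 390 and 215 of them shared with the fit without it. Deviations of same-numbered arrays correlated at 0.19, -0.07 and 0.17. The values for numbers 1 and 3 were the highest between the groups, while vehicle replicate 2 correlated best with another number. So few arrays cannot decide whether the numbers pair them. The other alternatives gave 361 to 441 higher and 167 to 259 lower genes, and quantile normalization shared 366 and 184 of the called genes.

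Against 3 gene lists called, an estimated correlation gave 1, fry 7, and leaving out CD14, CAMP, THBD and FBP1 from the lists 1. Leaving out 1 array gave 1 to 5, with 1 without vehicle replicate 3 or 1,25D replicate 3 and 5 without 1,25D replicate 1. The real split of the arrays called 3 lists and the highest other split 1, with 10 splits too few for a share under 0.05. The shorter lists show that CD14 and CAMP carried the antimicrobial call and CD14 the monocyte call, and otherwise the cause was not tested. The antimicrobial list also lost its call under the replicate block (adjusted p = 0.0527), with the mean of probes (0.0774), quantile normalization (0.0693) and cyclic loess (0.0935), over a range of 0.00149 to 0.578. Cholesterol synthesis was called in 4 of 17 alternatives, without the filter, with the mean of probes and without vehicle replicate 2 or 1,25D replicate 1 (adjusted p 0.0249 to 0.377 over all), and the NF-kB list in 3 of 17, above the 75th percentile and without 1,25D replicate 1 or 2 (0.0167 to 0.875 over all).

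Called named genes kept their direction and side in 782 fits over all alternatives and lost their call in 33, with MVD losing it in 8 of 16 and HMGCS1 in 4 of 16. IL1RN (adjusted p = 0.109, range 0.00607 to 0.109) and BCL2 (adjusted p = 0.199, range 0.00316 to 0.199) were lost with the mean of probes. Less THBD, its largest change, the coagulation list went from 0.10 to -0.0014 by construction. The other reversals came from values near 0, none of the reversed values was called, and their cause was not tested. GAPDH was 0.0223 and the vitamin D list -6e-04 with the mean of probes. CYP27B1 was 1e-04 after median centring, and MHC class II was 0.0064 and DNA replication 0.0066 after cyclic loess. Leaving out 1 array gave -0.0453 to 0.043 for CYP27B1, -0.004 to 0.0074 for the vitamin D list, -0.0246 to 0.0022 for interferon, -0.0101 to 0.0038 for MHC class II, -0.015 to 0.0033 for DNA replication, -0.0033 to 0.0075 for cholesterol efflux and -0.0109 to 0.0161 for calcium transport.

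Not run for lack of mapped unnormalized columns were other background corrections, neqc with median scaling or cyclic loess, and filters on detection p-values, and no slide was given to block on. Signal over background is therefore unknown, which limits statements on dim genes such as CYP24A1.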

Other observations

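The gene families and single genes of the next 2 paragraphs were chosen after their values were seen, as were the tests of neighbouring genes matched on intensity and of pairs without overlap, while the count of neighbouring pairs was planned before.

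Chemokines and their receptors stood out among 15 families grouped by symbol, with 4 of 40 tested genes higher and 2 lower (Fisher's exact test, adjusted p = 0.0257). Beside CXCL8 and CCL3, the chemokine receptor CCR1 rose by 1.02 and CXCL6 by 0.26, while the receptors CXCR3 and CXCR4 fell by 0.30 and 0.26, CXCR4 with -0.12 and no call in its dimmer probe. The family's mean was not called (camera, adjusted p = 0.204). Genes of RAB, DENND and TBC1D membrane trafficking had 6 higher and 6 lower of 112 (Fisher's exact test, adjusted p = 0.0146), among them DENND6B. Zinc finger genes of the ZNF series were called less often than all genes, with 2 higher and 3 lower of 402 (Fisher's exact test, adjusted p = 0.0146). The shares of these families were not matched on intensity. No histone gene of 52 and no proteasome subunit of 33 was called by limma.

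Further genes outside the rule for named genes were also called. The endocytic scaffold ITSN1 rose by 1.18 in its brightest probe, with a further probe at 0.0034 not called, the elongation factor ELL2 by 1.09, the protein kinase C substrate MARCKS by 1.05 and the coactivator PPARGC1B by 1.03. The metalloprotease ADAM19 rose by 0.89, PRKCH, a protein kinase C, by 0.87, the semaphorin SEMA4D by 0.86 and the secreted glycoprotein LRG1 by 0.82. Lower genes included the death ligand TNFSF10 at -0.31, the interleukin receptor IL17RA at -0.33, the lectin receptor CLEC12A at -0.33 and the nucleotide receptor P2RY2 at -0.35, the last with dimmer probes at 0.0028 and 0.06 that were not called. The limma adjusted p was 0.0113 for CLEC12A and smaller for the other 11 genes of this paragraph.

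In 3 genes a difference of at least 1.5-fold was not called because vehicle arrays spread widely. RHOQ read 6.20, 10.04 and 10.77 on the vehicle arrays and 10.99 to 11.05 with 1,25D (limma, adjusted p = 0.225). IFNGR2 read 10.21, 10.98 and 11.79 in vehicle against 11.903 to 11.999 (limma, adjusted p = 0.0662), and WHR1 read 8.71, 9.40 and 9.78 against 9.96 to 10.01 (limma, adjusted p = 0.0518). In all 3 genes the vehicle values rose in order from replicate 1 to replicate 3. The lowest RHOQ value lay near that array's minimum of 6.12. The cause of this shared order was not tested.

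Genes that rose with 1,25D lay next to each other more often than random placement gives. Among neighbouring tested genes without a shared name stem by the rule applied, 31 pairs were both higher. The median was 9 and the highest 23 in 10000 random placements (permutation p = 1e-04, the smallest they can give). The rule left in some like-named family members, among them NAPSB beside NAPSA (0.36 and 0.28) and ACVRL1 beside ACVR1B (0.24 and 0.33). Whether a probe read both members of such a pair was not tested. The count of 31 also lay above the highest of 26 when calls were placed among genes of like intensity. That argues against clustering of expressed genes as the whole cause. The 29 pairs without overlapping spans lay above 23, which argues against overlapping genes as the whole cause. Transcripts shared by neighbours whose spans do not overlap were not tested. The longest run was FGD3, SUSD3, CARD19 and NINJ1, which rose by 0.84, 0.33, 1.08 and 2.09. THBD stood beside CD93, CAMP beside ZNF589 (0.64), ITPR1 beside BHLHE40 (0.54), PDZD7 (0.98) beside SFXN3 (0.88), and ZFP36 between MED29 (0.19) and PLEKHG2 (0.19). Lower genes formed 7 such pairs against a median of 3 (permutation p = 0.0299, and 0.0428 matched on intensity), among them GFI1 and RPAP2. A hypothesis is that some VDR-responsive regulatory regions may act on several neighbouring genes. The arrays hold no binding data, so this was not tested beyond the counts.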
